A study of Mus musculus and Mus musculus x Mus spretus with 14 samples.

How the data were processed

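MicroRNA levels were measured on Exiqon arrays in 13 mouse skin cell lines, with 1 array per line and 2 arrays for line A5, 14 arrays in all. Per the labels' protocols, the lines were grown in serum-containing medium, total RNA was isolated with a Qiagen miRNA kit, and the RNA was labelled with the Exiqon kit and the dye Cy3. The values used are the deposited log2 signals, 1271 probes by 14 arrays with 0 missing values. That they are on a log2 scale was read from the values, which run from 5.93 to 15.2. The scanner, the background correction, the averaging of replicate spots and the normalization are not given in the sources used here, so the normalization method, the centring and any offset remain unknown. The medians of the 14 columns over all probes lay between 6.71 and 6.86 (C5N 6.86, C50 6.76, NK 6.77, MSCP1 6.71, P6 6.77, B9 6.78, E4 6.75, PDVC57 6.77, A5 6.82 and 6.79, D3 6.78, CARB 6.76, CARC 6.77, H11 6.78), and the deposited columns were therefore used without further scaling. These medians lie near background, so their agreement does not show that the brighter miRNAs share a scale across arrays. The SD over mouse probes ran from 0.55 on MSCP1 to 1.42 on B9. Differences are given on the log2 scale. Levels near the median of the 8 negative control probes, 6.50 to 6.71 by array, lie at background, so a difference against a group at that level understates the change in the miRNA. The number of arrays, not a read depth, limits the precision.

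Groups were taken from the phenotype given for each line in the labels: 5 non-malignant squamous lines (the immortalized keratinocyte lines C5N, C50 and NK and the papilloma lines MSCP1 and P6), 3 malignant squamous lines (B9, E4 and PDVC57) and 5 malignant spindle lines (A5, D3, CARB, CARC and H11). Among 91 pairs of arrays at most 2 values were identical. The 2 A5 arrays were averaged and counted as 1 line. Each line counted as 1 sample, and p-values measure the spread between lines. The labels state that B9, A5 and D3 came from 1 tumour and E4 and H11 from another, so the lines are not all independent. The labels disagree on whether lines NK and P6 come from a cross with Mus spretus, and both readings were tried as a covariate.

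Of the probes, 576 name a mouse miRNA (568 different names) and were tested. The 125 control or undisclosed probes and the 570 other probes, 89 of them for viral miRNAs, were left out of the tests, apart from an alternative with all miRNA probes. Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, Benjamini-Hochberg adjustment over the 576 probes, adjusted p of 0.05), with all 13 lines sharing one estimate of the spread, except within tumours, where the 5 lines of the 2 tumours were fitted. Spindle lines were compared with each squamous group and with the equally weighted mean of both squamous groups. Malignant squamous lines were compared with non-malignant squamous lines, and papilloma with immortalized keratinocyte lines. Within tumours the tumour was a fixed block. For miR-203 and miR-205, named in the series title, exact two-sided permutation tests of the difference in means were run over all splits of the lines, with Benjamini-Hochberg adjustment over the family of 8 tests.

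The lists of miRNAs were fixed before the data were examined: the miRNAs of the series title, the miR-200 family, the cluster of miR-183, miR-96 and miR-182, other epithelial and keratinocyte miRNAs, fibroblast and mesenchymal miRNAs, the imprinted Dlk1-Dio3 cluster, the cluster in an Sfmbt2 intron, the miR-17-92 cluster and paralogs, the let-7, miR-34 and miR-449, miR-15 and miR-16, miR-29, miR-30 and miR-181 families, the clusters of miR-23, miR-27 and miR-24, the group of miR-99, miR-100, miR-125 and miR-10, the cluster of miR-221 and miR-222, miRNAs associated with invasion and TGF-beta, and markers of blood, endothelial, muscle, neural, pluripotent and liver cells. Of these 24 lists, 23 had at least 2 measured members. They were tested with limma camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry's directional test, adjusted over the lists. Members were also counted after adjustment over all probes and over the list alone. The miRNAs named in each comparison followed a rule set before the data were examined: miR-203 and miR-205, then the up to 10 largest changes in each direction with an adjusted p under 0.05 and no overlap between the groups, or, where a direction had none, the 3 with the smallest p given as values, then up to 4 members with the smallest p of each list described. A miRNA with several probes was represented by its brightest probe. Star forms were not matched to the lists. A table of gene symbols for the mouse genome was not used here.

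The limma steps were tested on simulated log2 values built on the real means and residual spread of the 576 probes, with 20 runs per comparison. In the simulation of spindle against non-malignant squamous lines, 68.5% of probes changed by 1 log2 unit, 89.0% of those changed by 2 and 97.5% of those changed by 3 were recovered, and 4.58% of calls were false. Within tumours 39.0, 50.5 and 71.8% were recovered, and 46.8, 76.0 and 92.2% for papilloma against immortalized lines. The changed probes were drawn at random, and most probes vary little between lines. Each run held 20 changed probes of each size, and the noise was independent and equal across lines, without outlying arrays or related lines. Recovery in the real data may therefore be lower. Alternatives fixed beforehand were quantile normalization, centring on the median, keeping the brighter probes, all miRNA probes, other variance models, either A5 array alone, leaving out each line in turn, only the groups compared, the tumour as a random or fixed block, and the Mus spretus cross as a covariate. Added after seeing the data were fits without lines C5N, MSCP1 and A5, fits without C5N and MSCP1, limma array weights, and the mean of the 10 spike-in probes as a covariate. Array weights were first estimated by REML, which stopped before convergence in 5 of 6 fits. The gene-by-gene estimator was added after the REML counts had been seen, and both are reported.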

Results

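The data consist of miRNA array profiles of 13 mouse skin cell lines from different stages of skin carcinogenesis. Non-malignant squamous lines (n = 5) comprised 3 immortalized keratinocyte lines and 2 papilloma lines. Malignant squamous lines (n = 3) and malignant spindle lines (n = 5) came from skin tumours, spindle cells being those that have lost epithelial morphology. The series title places miR-203 and miR-205 in the context of prognosis of cutaneous squamous cell carcinoma. The 2 arrays of spindle line A5 correlated at r = 0.994 across probes, with a median absolute difference of 0.11 on the log2 scale.

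Arrays of 3 lines stood apart from the rest. The array of the immortalized line C5N had a median correlation of 0.332 across probes with the other arrays, and its let-7a and miR-21 levels were 6.99 and 7.01. miR-671-3p and miR-19a* reached 14.49 and 14.43 on it, and at most 7.91 and 8.05 in the other lines. The array of the papilloma line MSCP1 had the smallest spread over mouse probes (SD 0.55). On it 37 probes lay more than 1 log2 unit above the median of the negative controls, against 119 to 185 on the other arrays. That median hides 1 bright control probe, at 7.74 on MSCP1 and 8.45 to 11.5 on the other arrays. On both arrays of spindle line A5, with median correlations of 0.735 and 0.747, let-7a stood at 7.61 and 7.50, and miR-21 at 8.56 and 8.25. In the other 10 lines let-7a lay between 9.87 and 10.5. These lines belong to the non-malignant and spindle groups, so they move with every comparison that includes those groups. Spike-in probes averaged 9.17 ± 0.94 (SD, n = 5) in spindle and 8.45 ± 0.70 (n = 5) in non-malignant squamous lines, and the difference of 0.82 between spindle and all squamous lines had an exact permutation p of 0.0707. A first probe for U6 RNA (U6-snRNA-2), a control for RNA input, stood at 13.03 ± 0.98 in spindle, 13.81 ± 1.09 (n = 3) in malignant squamous and 11.78 ± 1.33 in non-malignant squamous lines. It was lowest in C5N (10.45) and MSCP1 (10.42). A second U6 probe (U6-snRNA-1) read 11.24 to 12.18 in malignant squamous, 9.78 to 11.97 in spindle and 6.48 (C5N) to 10.50 in non-malignant squamous lines.

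**Figure D1:**
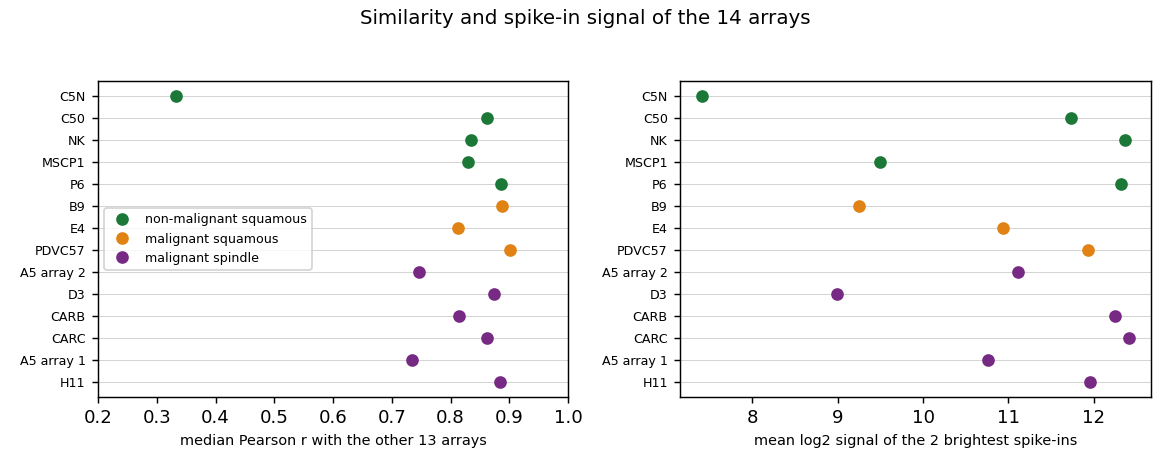
Array-level measures for the 14 arrays, coloured by group. The left panel gives the median Pearson correlation with the other arrays over mouse miRNA probes, lowest at 0.332 for C5N. The right panel gives the mean log2 signal of spike-in controls i and j, labelled there as the 2 brightest, lowest at 7.41 for C5N. On C5N this mean lies below that of all 10 spike-in probes (7.67).

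miR-205, a miRNA of stratified epithelia, fell in spindle lines. Its level was 6.92 ± 0.31 (SD, n = 5) in spindle lines and 9.73 ± 1.75 (n = 8) in squamous lines, a difference of -2.81, with 5 of 5 spindle lines under the squamous mean (exact two-sided permutation p = 0.00777, adjusted p = 0.0318 over 8 tests). Against the 5 non-malignant squamous lines alone the difference was -3.14 (exact permutation p = 0.00794, adjusted p = 0.0318). Malignant squamous lines had 9.17 ± 2.21 (n = 3), and neither their difference from spindle lines (-2.25, exact permutation p = 0.0893) nor from non-malignant lines (-0.89, exact permutation p = 0.554) passed the test, where the smallest p these group sizes allow was 0.0179. The malignant squamous line E4 had miR-205 at 6.69, in the range of the spindle lines, while B9 and PDVC57 had 10.94 and 9.87. Without E4 the malignant squamous minus non-malignant difference was 0.34. The spindle minus malignant squamous difference was -3.49 without E4 and -1.36 without B9.

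miR-203, which promotes keratinocyte differentiation, did not pass the exact tests. It was 6.98 ± 0.16 (n = 5) in spindle, 6.95 ± 0.15 (n = 3) in malignant squamous and 8.00 ± 1.32 (n = 5) in non-malignant squamous lines. The exact permutation p was 0.264 for spindle against all squamous lines (difference -0.62) and 0.0635 for spindle against non-malignant lines (difference -1.02). Levels above 8 were seen in the immortalized lines NK (10.16) and C50 (8.27), and without NK the spindle minus squamous difference was -0.26. For the pair of title miRNAs in spindle against non-malignant lines, limma gave 2 of 2 lower when adjusted over the list alone and 0 when adjusted over all probes. miR-203 passed adjusted over the list alone in 3 of 13 fits without 1 line, those without C5N, MSCP1 or P6, while miR-205 passed in 13 of 13. Without NK the miR-203 difference from non-malignant lines was -0.47, and it did not pass.

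**Figure D2:**
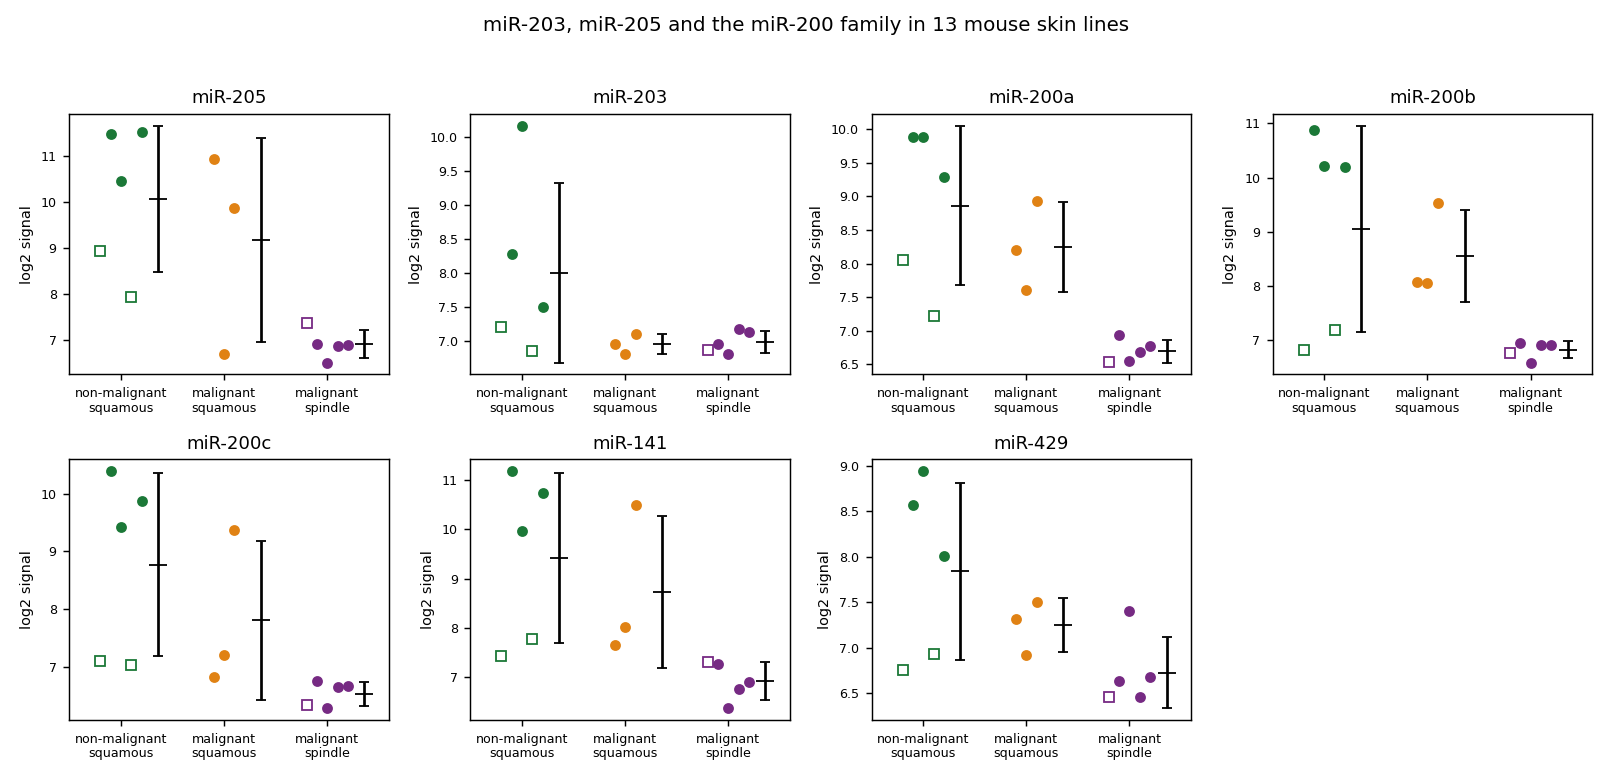
Log2 signal of miR-205, miR-203 and the miR-200 family in each line by group, with the mean and SD of each group as black bars. Open squares are lines C5N, MSCP1 and A5, and the spindle lines lie near 7 for miR-205 with a mean of 6.92, on vertical axes that differ between panels and do not start at 0.

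The spindle lines were compared with non-malignant squamous lines to contrast the ends of the phenotype series. The miR-200 family, which restrains Zeb1 and Zeb2 and maintains the epithelial state, fell in spindle lines. All 5 members were lower, by -2.05 on average, and 5 passed when adjusted over the list alone, while 0 passed over all probes. miR-141 differed by -2.50 ± 0.74 (SE), miR-200c by -2.23 ± 0.65, miR-200b by -2.23 ± 0.71 and miR-200a by -2.17 ± 0.48, each lower in 5 of 5 spindle lines than the non-malignant mean. Camera gave an adjusted p of 3.31e-08 for the family, against an adjusted p of 0.111 with an estimated correlation, and fry's directional adjusted p was 0.0484. The estimated correlation between the members was 0.862, against the preset 0.01, so the 5 members are far from independent results. The pair of title miRNAs had a camera adjusted p of 0.00292, an adjusted p of 0.111 with an estimated correlation and a fry adjusted p of 0.0484. The spindle means of miR-141, miR-200a, miR-200b and miR-200c, 6.54 to 6.92, lay near the negative control level.

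The miR-29 family, which targets collagen and other matrix transcripts, was higher in spindle than in non-malignant squamous lines. All 3 members passed adjusted over the list alone: miR-29a by 2.09 ± 0.64 (SE), miR-29b by 2.04 ± 0.70 and miR-29c by 1.59 ± 0.43. The first U6 probe differed by 1.25 between these groups (exact permutation p = 0.159). The camera adjusted p of the miR-29 family was 3.79e-04, the adjusted p with an estimated correlation 0.113, and fry's adjusted p 0.034. Of 7 fibroblast and mesenchymal probes, 6 were higher and 3 passed adjusted over the list alone: miR-143 (1.62 ± 0.43), miR-145 (0.77 ± 0.26) and the probe shared by miR-199a-3p and miR-199b (1.32 ± 0.46). The camera adjusted p of that list was 3.79e-04, the adjusted p with an estimated correlation 0.111, and fry's adjusted p 0.034, and with quantile normalization 1 member passed over the list alone. Without C5N, MSCP1 and A5 the differences were 1.23 for miR-29a, 1.25 for miR-29b and 1.31 for miR-29c, a mean of 1.26 against 1.91 with all lines, and 1 passed over the list alone. All 13 let-7 probes were higher, by 0.88 on average, none past the threshold over the list alone. The let-7 list had a camera adjusted p of 3.15e-04, an adjusted p of 0.509 with an estimated correlation and a fry adjusted p of 0.173, and let-7a lay at 6.99 and 7.34 on the arrays of C5N and MSCP1. The mean let-7 difference was 0.34 without C5N, MSCP1 and A5.

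Over all 576 probes limma called 0 in spindle against non-malignant squamous lines, with a smallest adjusted p of 0.262. At an unadjusted p under 0.05 there were 49 probes (32 higher, 17 lower), where chance gives 28.8, and 6 probes (1.04%) did not overlap between the groups, against 0.794% by chance. Without lines C5N, MSCP1 and A5, limma called 7: miR-141 (-3.80), miR-200a (-2.95), miR-200b (-3.59), miR-200c (-3.31), miR-429 (-1.71) and miR-205 (-4.35) lower and miR-143 (2.03) higher. These 3 lines were set aside after the data were seen, and C5N and MSCP1 are the lowest non-malignant lines for miR-200b, at 6.81 and 7.18, so that leaving them out raises the level of the reference group. A5 is the lowest spindle line for miR-143, at 6.69, so that leaving it out raises the spindle level. Quantile normalization called 2 (miR-200a and miR-205), and leaving out MSCP1 alone called 1 (miR-200a).

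Spindle lines were also compared with squamous lines irrespective of malignancy. All 7 fibroblast and mesenchymal probes were higher in spindle lines, and 5 passed the threshold adjusted over the list alone. The largest differences were in miR-143 (1.68 ± 0.39, SE), the miR-199a-3p and miR-199b probe (1.41 ± 0.42), miR-199a-5p (0.99 ± 0.35) and miR-145 (0.78 ± 0.24). miR-143 and miR-145 come from one precursor transcript and are abundant in smooth muscle and fibroblasts. The list had a camera adjusted p of 1.82e-06, an adjusted p of 0.0685 with an estimated correlation and a fry adjusted p of 0.0286, and with quantile normalization 6 of the 7 probes were higher and 3 passed over the list alone. Among spindle lines miR-143 ranged from 6.69 in A5 to 9.32 in CARC.

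The miR-200 family was lower in spindle than in all squamous lines, with 5 of 5 members past the threshold adjusted over the list alone and a mean difference of -1.71. miR-141 (-2.15 ± 0.68, SE), miR-200a (-1.86 ± 0.44) and miR-200c (-1.75 ± 0.60) were the 3 of 576 probes (0.521%) whose levels did not overlap between the groups, against 0.155% by chance. The family had a camera adjusted p of 2.66e-08, and the adjusted p was 0.153 both with an estimated correlation and with fry. The pair of title miRNAs, the cluster of miR-183, miR-96 and miR-182, the let-7 and miR-29 families and the neural list passed camera with adjusted p of 0.0164, 0.0435, 0.00678, 0.0309 and 0.0185. With an estimated correlation their adjusted p were 0.209, 0.506, 0.507, 0.464 and 0.478, and with fry 0.228, 0.365, 0.365, 0.232 and 0.349. miR-29c (1.13 ± 0.40), miR-9 (0.70 ± 0.21) and, in the family of miR-15 and miR-16, miR-322 (0.66 ± 0.18) were higher adjusted over the list alone, miR-9 not with quantile normalization.

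The other lists did not pass camera in spindle against all squamous lines. Adjusted p were 0.728 for the other epithelial and keratinocyte miRNAs, 0.212 for the Dlk1-Dio3 cluster, 0.0743 for the Sfmbt2 cluster, 0.102 for the miR-17-92 cluster, 0.212 for the family of miR-34 and miR-449 and 0.0906 for the family of miR-15 and miR-16. They were 0.193 for the miR-30 family, 0.707 for the clusters of miR-23, miR-27 and miR-24, 0.728 for the group of miR-99, miR-100, miR-125 and miR-10, 0.821 for the cluster of miR-221 and miR-222, 0.212 for the miR-181 family and 0.732 for the invasion and TGF-beta list. Marker lists of other cell types gave 0.675 for blood, 0.335 for endothelial, 0.12 for muscle and 0.212 for pluripotent cells, and the single liver marker differed by -0.20. Over all probes limma called 0, with a smallest adjusted p of 0.224 and 28 probes at an unadjusted p under 0.05 against 28.8 by chance. It called 8 without C5N, MSCP1 and A5, 2 without A5 alone (miR-143 and miR-322), 1 without MSCP1 alone (miR-200a) and 2 with quantile normalization. A5 was the lowest spindle line for miR-143 (6.69) and miR-322 (6.79), so leaving it out had to enlarge both differences.

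**Figure D3:**
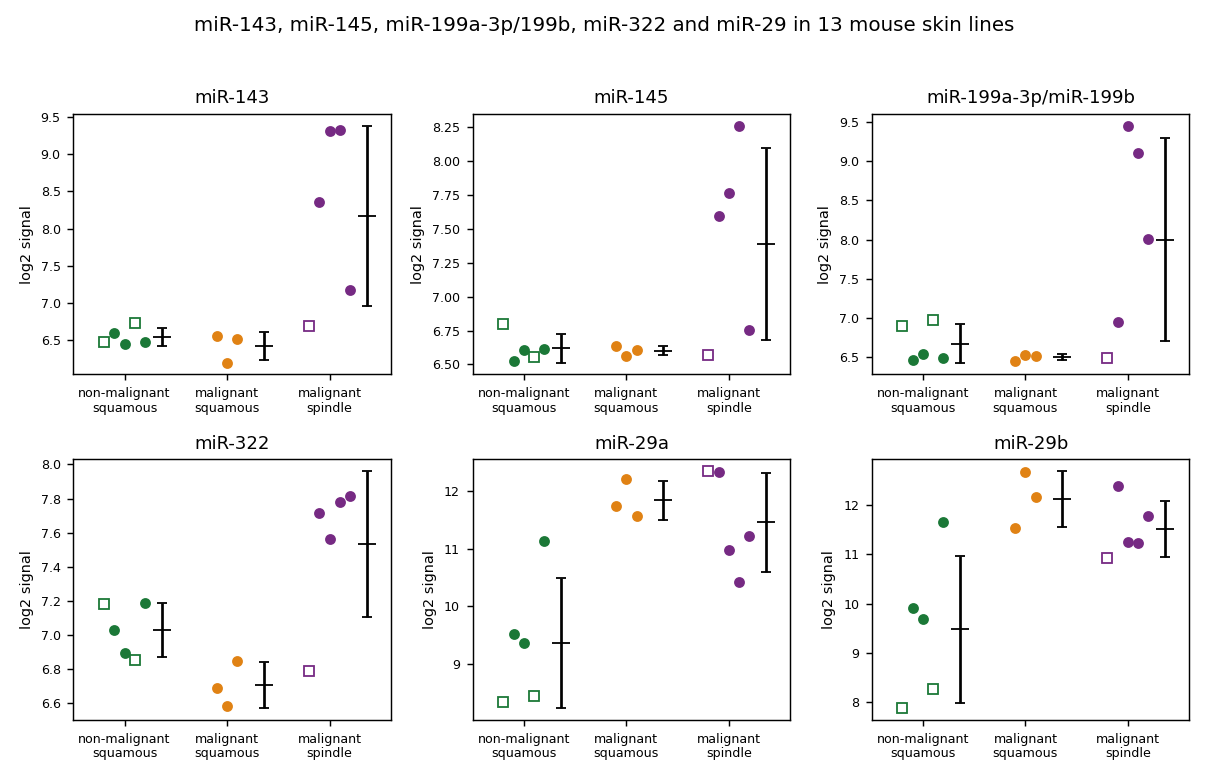
Log2 signal of miR-143, miR-145, the miR-199a-3p/miR-199b probe, miR-322, miR-29a and miR-29b in each line by group, with the mean and SD of each group as black bars and lines C5N, MSCP1 and A5 as open squares. Within the spindle group miR-143 runs from 6.69 in A5 to 9.32 in CARC, and vertical axes differ between panels and do not start at 0.

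Within malignancy, spindle lines were set against malignant squamous lines. All 7 fibroblast and mesenchymal probes were higher, and 4 of them passed the threshold adjusted over the list alone: miR-143 (1.75 ± 0.49, SE), the miR-199a-3p and miR-199b probe (8.00 ± 1.30, SD, against 6.50 ± 0.04), miR-199a-5p (1.15 ± 0.45) and miR-145 (0.78 ± 0.30). The list had a camera adjusted p of 4.64e-06, an adjusted p of 0.0724 with an estimated correlation and a fry adjusted p of 0.106, and with quantile normalization 0 passed over the list alone. All 5 miR-200 probes were lower, by -1.37 on average, with miR-200a at 6.69 ± 0.17 (SD, n = 5) in spindle and 8.24 ± 0.67 (n = 3) in malignant squamous lines, and 0 passed over the list alone, against 4 without C5N, MSCP1 and A5. Camera adjusted p were 0.000133 for the miR-200 family, 0.00914 for the cluster of miR-183, miR-96 and miR-182, 0.00128 for the miR-17-92 cluster and 0.0174 for the neural list, and the adjusted p was 0.503 for each of these with an estimated correlation and 0.558 with fry. miR-182 (-1.28), miR-106b (-1.65) and miR-9 (0.68) were the members with the smallest p in the last 3 lists.

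Over all probes limma called 0 in spindle against malignant squamous lines, with a smallest adjusted p of 0.939 and 17 probes at an unadjusted p under 0.05. No overlap between the groups was seen for 22 probes (3.82%), against 3.57% by chance. The smallest p were those of miR-322 (0.83 ± 0.23, SE, past the threshold adjusted over the list alone in the family of miR-15 and miR-16), miR-143 and the miR-199a-3p and miR-199b probe among higher miRNAs, and of miR-362-5p (-0.43), miR-200a (-1.55) and miR-93* (-0.31) among lower ones. Without A5 limma called 1, miR-322, with a difference of 1.01, and it called 1 without C5N, MSCP1 and A5. A5 was the lowest spindle line for miR-322 (6.79 against 7.56 to 7.82), so leaving it out had to enlarge that difference. With array weights limma called 3 by one estimator, which did not converge, and 1 by the other.

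Malignant squamous lines were compared with non-malignant squamous lines at matched morphology. All 3 members of the miR-29 family were higher, and 2 passed the threshold adjusted over the list alone, miR-29b by 2.65 ± 0.81 (SE) and miR-29a by 2.47 ± 0.74. miR-222 (2.00 ± 0.75) and miR-221 (1.89 ± 0.74), which repress the cell cycle inhibitor p27, also passed adjusted over the list alone. The first U6 probe was higher by 2.03 in malignant squamous lines (exact permutation p = 0.0536), as much as the mean differences of miR-29 (2.01) and of miR-221 and miR-222 (1.94). On the second U6 probe all malignant squamous lines (11.24 to 12.18) lay above all non-malignant lines (6.48 to 10.50), with C5N lowest. Camera adjusted p were 0.00186 for miR-29, 0.0105 for miR-221 and miR-222, 0.00432 for the miR-17-92 cluster, 0.0105 for let-7, 0.00994 for the invasion and TGF-beta list and 0.0482 for the miR-200 family. With an estimated correlation the adjusted p were 0.483, 0.485, 0.69, 0.69, 0.582 and 0.69, and with fry 0.112, 0.196, 0.493, 0.676, 0.493 and 0.843. The arrays of C5N and MSCP1 had miR-29a at 8.34 and 8.45, below the other non-malignant lines, which had 9.37 to 11.1.

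Without C5N, MSCP1 and A5 the mean differences in malignant against non-malignant squamous lines were 1.32 for miR-29, with 2 members past the threshold over the list alone, and 1.12 for miR-221 and miR-222, with 0. Those of the let-7 and miR-17-92 lists were 0.07 and 0.29, and 3 lists passed camera against 6 with all lines. With quantile normalization of all lines the mean differences were 1.27 for miR-29 and 1.24 for miR-221 and miR-222, with 0 members of either list past the threshold over the list alone. The miR-200 family differed by -0.68 with all lines and by -1.71 without these lines, where 5 of 5 passed over the list alone. C5N and MSCP1 averaged 7.51 and 7.35 over the family and miR-205, against 10.1 in the other non-malignant lines. Leaving them out therefore had to enlarge the fall, so the 5 calls test nothing. Over all probes limma called 0 with all lines, with a smallest adjusted p of 0.844, 26 probes at an unadjusted p under 0.05 and 28 (4.86%) without overlap, against 3.57% by chance, and 0 under each alternative run.

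Within the tumours that yielded both morphologies, miR-200a and miR-200b were lower in each spindle line than in the squamous line of the same tumour. miR-200b differed by -1.31 in A5 and -1.13 in D3 relative to B9, and by -1.13 in H11 relative to E4. For miR-200a these differences were -1.66, -1.26 and -0.83. In the blocked limma fit the differences were -1.18 ± 0.33 (SE) for miR-200b and -1.19 ± 0.34 for miR-200a, with an adjusted p of 0.0328 for both adjusted over the list alone and 0.981 over all probes. That fit rests on 5 lines from 2 tumours, with A5 and D3 both set against B9, so few lines give its spread. miR-143 differed by 0.97 ± 0.51 and miR-205 by -2.08 ± 0.92, without passing, and without B9 the miR-205 difference was 0.21. Limma called 0 probes with 7 at an unadjusted p under 0.05 and 67 (11.6%) without overlap, against 20% by chance, and 2 without B9 (let-7g* and miR-20b*) or without H11 (miR-153 and miR-181c), which were named after their values were seen. The overlap was counted over 3 spindle and 2 squamous lines pooled over the tumours. Its chance share takes the 5 lines as exchangeable, so neither describes the comparison within tumours. Without B9 the comparison rests on H11 against E4, and without H11 on A5 and D3 against B9. Leaving out E4 gives the same comparison as leaving out H11, and there miR-153 and miR-181c were not called. In each of these fits 1 degree of freedom per probe, from A5 and D3, gives the spread, which limma moderates over all probes. The lone lines are assumed to vary like that pair.

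Papilloma lines were compared with immortalized keratinocyte lines as the kinds of non-malignant line. The members of the miR-200 family with the smallest p, miR-200a and miR-429, differed by -1.02 ± 0.66 (SE) and -0.62 ± 0.55, miR-203 by -1.37 ± 0.60 and miR-205 by -0.57 ± 1.20, none of them past the threshold. The miR-203 difference was -0.56 without NK and -2.05 without C5N, where it passed adjusted over the list alone. Without MSCP1 the miR-200a and miR-205 differences were 0.02 and 1.22, with P6 as the lone papilloma line, assumed to vary like the other groups. miR-146a, an inhibitor of NF-kappaB signalling, was 7.36 ± 0.37 (SD, n = 2) in papilloma and 6.58 ± 0.08 (n = 3) in immortalized lines. Limma called 0 probes, with a smallest adjusted p of 0.999 and 14 at an unadjusted p under 0.05, all of them lower in papilloma lines, and 59 (10.2%) did not overlap, against 20% by chance. Without C50 it called 1, miR-224 (-1.05), named after its value was seen. Each kind includes a line with an outlying array, MSCP1 or C5N.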

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

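The tests without lines C5N, MSCP1 and A5, without A5 alone, of labelling on the spindle, C5N and A5 arrays, of the Mus spretus cross, of the noise of a single hybridisation on A5, and the splits without the 3 lines were chosen only after the results were seen, and the spike-in covariate was added after the data were seen but before its own result was.

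The fall of the miR-200 family and miR-205 in spindle relative to non-malignant squamous lines was -2.23 ± 0.64 (SE) as a mean over the 6 miRNAs. Without A5 it was -2.24 ± 0.72, and among the lines without a Mus spretus cross it was -2.52 ± 0.92 by the description and -2.57 ± 0.94 by the organism field, which argues against the A5 array and the cross as its source. It was -3.29 without all 3 lines and -2.75 with the spike-in mean as a covariate, which test nothing, because C5N and MSCP1 were low both in spike-in signal and in the 6 miRNAs (7.51 and 7.35 against 10.1 in the other non-malignant lines), so both settings had to enlarge the fall. The spike-in mean was higher by 0.72 ± 0.52 in spindle lines, which argues against weaker labelling there, and the 100 brightest other mouse probes had a median difference of 0.56, and of -0.14 without the 3 lines, too small for a general loss of signal. A loss of these epithelial miRNAs in spindle cells, relatedness of the lines, culture and strain differences other than the cross stay open.

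The weak correlation of the C5N array with all others was set against misplaced probe names and weak labelling. Shifting the column by up to 50 positions gave a correlation of at most 0.094 with the mean of the other lines, against 0.38 unshifted, which argues against a shift of that kind. The 50 miRNAs brightest elsewhere differed by -1.96 on average. Spike-in controls i and j averaged 7.41 on C5N, against 8.99 to 12.4 on the other arrays. The mean of all 10 spike-in probes on C5N, 7.67, lay within the 7.63 to 10.02 of the others. Controls i and j thus lay below the mean of all 10 spike-in probes on C5N, but above it on every other array. On C5N 28 mouse probes lay more than 1 log2 unit above every other line, among them miR-671-3p and miR-19a* at 14.49 and 14.43, against at most 11 for any other line, which argues against weak labelling as the whole cause. Weak labelling together with another fault of the array stays open, and no biological explanation was tested.

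Both A5 arrays were low in let-7a and miR-21. The 2 arrays correlated at 0.9936, against at most 0.822 with any other line, so noise of a single hybridisation is not a candidate cause. Relative to the other lines let-7a and miR-21 differed by -2.85 on average, while the 50 other brightest miRNAs had a median difference of 0.29 (SD of the differences 1.79), with 27 higher and 23 lower on both arrays. Spike-in controls i and j differed by 0.017 on average, so these values argue against weak labelling, which would lower the bright miRNAs together. A negative control probe read 11.5 and 11.2 on the A5 arrays, against 7.74 to 9.28 on the other arrays, and the cause of that signal was not tested. Labelling that depends on the sequence and a feature of line A5 itself stay open and untested.

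Single lines lay far from the other lines of their group for 8 of 112 combinations of a named miRNA and a group of 5 lines. Chance gives about 1 in 20. In A5, let-7a was 7.56 against 9.87 to 10.5 in the other spindle lines, and miR-322 was 6.79 against 7.56 to 7.82. In C5N, miR-363 was 7.58 against 6.59 to 6.88 and miR-322* was 7.30 against 6.34 to 6.46. In P6, miR-146b was 8.05 against 6.73 to 6.95. In D3, miR-146a was 7.96 against 6.47 to 6.81 and miR-470* was 6.23 against 6.45 to 6.53. In CARB, miR-429 was 7.40 against 6.46 to 6.68.

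miR-205 differences had opposite signs in the tumours with both morphologies: -3.56 in A5 and -4.02 in D3 relative to B9, and 0.21 in H11 relative to E4. E4 and H11 had miR-205 at 6.69 and 6.90, near their negative control medians of 6.50 and 6.64, so the value of 0.21 gives no direction. The difference between the tumours was not tested.

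With all 13 lines limma called 0 probes in each comparison of the phenotype groups, and all 56, 56, 100 and 100 splits examined reach a count of 0 by construction, so the splits say nothing about chance there. Of the other splits 4, 3, 3 and 4 called any probe, and the highest called 3 for spindle against malignant squamous, 13 for malignant against non-malignant squamous, 12 for spindle against non-malignant and 4 for spindle against all squamous lines. Without C5N, MSCP1 and A5, the 7 calls of spindle against non-malignant lines were reached by 1 of 35 splits, the real one, with 2 as the highest of the others. The 8 calls against all squamous lines were reached by 1 of 100, with 4 as the highest of the others. Chance is not excluded for either count, because the 10 lines were chosen after the data were seen and leaving out C5N and MSCP1 favours these calls. The 1 call against malignant squamous lines was reached by 5 of 35 splits, with 3 as the highest, and chance cannot be excluded.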

How the results depend on the processing

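The fits without C5N, MSCP1 and A5, without C5N and MSCP1, with array weights and with the spike-in covariate were chosen after seeing the data. All other alternatives were fixed before the data were examined. Of 3492 values of named miRNAs under an alternative, 3389 kept their direction and side of the threshold, 70 passed it newly and 33 changed sign. The threshold here was the adjusted p over all probes, which 0 probes passed in the main fits. No value could therefore lose a call, and the 3389 were short of the threshold in both fits, so this count does not measure robustness. The difference of miR-205 spindle against squamous lines stayed past the threshold in the exact test under all alternatives run, -3.24 to -2.55 when 1 line was left out, and that of miR-203 stayed short of it, -0.74 to -0.26. The cause was not tested for any change below, except where fewer lines explain it.

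Calls over all probes rose from 0 as follows. Quantile normalization gave 2 in spindle against non-malignant and 2 against all squamous lines. Without C5N, MSCP1 and A5 the counts were 7 and 8, and 1 against malignant squamous lines. Without C5N and MSCP1 they were 7 and 6. Array weights gave 9 and 11 with both estimators, and against malignant squamous lines 3 with REML, which stopped before convergence, and 1 with the gene-by-gene estimator chosen afterwards. Leaving out 1 line at a time gave 0 to 1 calls for spindle against malignant squamous, 0 to 1 against non-malignant, 0 to 2 against all squamous lines, 0 to 1 for papilloma against immortalized lines and 0 to 2 within tumours. Malignant against non-malignant squamous lines gave 0 under all alternatives run.

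Of the lists that passed camera (5, 6, 5 and 7 for spindle against malignant squamous, malignant against non-malignant squamous, spindle against non-malignant and spindle against all squamous lines), 0, 0, 0 and 0 passed with an estimated correlation, 0, 0, 4 and 1 with fry and 0, 0, 2 and 1 with fry and the tumour as a random block. Without C5N, MSCP1 and A5, 7, 3, 12 and 8 passed camera, 0, 0, 2 and 0 with an estimated correlation and 0, 0, 2 and 3 with fry. Without C5N and MSCP1, 3 and 11 passed for malignant and for spindle against non-malignant squamous lines, and gene-by-gene array weights gave 9 for the latter.

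Signs turned as follows, with ranges over fits without 1 line. For spindle against malignant squamous lines miR-203 ranged from -0.038 without E4 to 0.11, with -0.014 without CARC and -0.0032 without H11, and was -0.41 with the spike-in covariate. For malignant against non-malignant squamous lines miR-205 ranged from -1.78 to 0.34 without E4, and without C5N and MSCP1, with or without A5, the miR-199a-3p and miR-199b probe was 0.00083 and let-7a -0.061. For spindle against all squamous lines let-7e was -0.24 without C5N, MSCP1 and A5. Within tumours miR-205 ranged from -3.79 to 0.21 without B9, and miR-203 from -0.040 without E4 or H11 to 0.32.

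For papilloma against immortalized lines, miR-205 ranged from -2.36 to 1.22 without MSCP1, with 0.030 without C50, and was 0.48 with quantile normalization and 0.55 without C5N and MSCP1, with or without A5. miR-145 ranged from -0.12 to 0.018 without C5N, and was 0.022 with median centring, 0.25 with the Mus spretus cross by description, 0.047 without C5N and MSCP1, with or without A5, 0.014 with REML weights and 0.00975 with gene-by-gene weights. miR-200c ranged from -1.93 to 0.91 without MSCP1, with 0.19 without C50, and was 0.0031 with the cross by description. miR-200b ranged from -2.12 to 0.89 without MSCP1, with 0.18 without C50, and miR-200a from -2.06 to 0.019 without MSCP1, while miR-152 was -0.036 without C5N and MSCP1, with or without A5. The alternative on missing values changed nothing because all probes had all values. Signal over background limits the spindle levels of miR-205 and the miR-200 family.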

Other observations

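The following hypothesis was noticed in the data, and its tests were chosen afterwards. miR-322, miR-503, miR-351, miR-542 and miR-450 lie together on the X chromosome, and miR-322 is the mouse counterpart of miR-424. Of 9 probes of this cluster, 7 were higher in spindle than in all squamous lines, by 0.35 on average. miR-322 was 7.53 ± 0.43 (SD, n = 5) in spindle and 6.91 ± 0.22 (n = 8) in squamous lines, miR-503 was 8.50 ± 0.72 and 7.85 ± 0.41, and miR-542-3p was 8.35 ± 0.99 and 7.60 ± 0.55. Without miR-322 and miR-450a-5p, which drew attention first, the directional fry p over the other 7 probes was 0.0403, consistent with a shared change of the cluster. It was 0.0388 for spindle against non-malignant squamous lines and 0.158 against malignant squamous lines, which did not pass. Without lines C5N, MSCP1 and A5 the fry p against all squamous lines was 0.308 and the mean difference 0.10, so the hypothesis may rest on those arrays. miR-322 is the member that limma called without those lines. A5 was the lowest spindle line for miR-322, so leaving it out had to enlarge that difference.

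Among the 89 probes for viral miRNAs, 1 lay more than 1 log2 unit above the negative control median in all 13 lines and 27 did so in at least 1 line. No explanation for these signals was tested.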
